A study of Drosophila melanogaster with 12 samples.

How the data were processed

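GRO-seq libraries from SL2 cells treated with RNAi against GFP or MSL2 were used, with 2 biological replicates per treatment. Per the submitters' processing notes, reads were aligned with Bowtie to dm3. The Bowtie version and the alignment settings are not given in the sources used here. The deposited tables hold 1 aligned read per line, with name, strand, chromosome, position counted from 0, sequence, quality, number of other positions and mismatches. They are neither counts nor a normalized unit. All reads were 36 bases long, and at least 99.99% of the reads of each lane had 1 position. The lanes differed in the mismatches allowed. The highest number seen was 10 in lane 1 of replicate 1, 2 in lane 1 of replicate 2 and 1 in the other 8 lanes, for both treatments alike. Read names place those 8 lanes on 1 flow cell and each pair of first lanes on another instrument.

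Lanes of 1 library were summed and not treated as replicates. Within the shared flow cell, lanes of 1 library differed by sampling noise, with a chi-square per degree of freedom of 1.00 to 1.09 over units. First lanes differed from the later lanes of their library by 1.69 to 3.01. With lanes summed, the 2 libraries of a treatment differed by 27.6 in controls and 28.1 after MSL2 RNAi. This measure grows with depth. Between single lanes of the shared flow cell, libraries of 1 treatment differed by 16.4 to 17.2. Libraries of different treatments with the same replicate number differed by less, 14.4 to 15.0 for replicate 1 and 11.9 for replicate 2. Those that differed in both treatment and number differed by 22.4 to 24.4. Since libraries differed by more than lanes did, p-values of single units rest on the spread between 2 libraries per treatment. Reads were counted by their first base, and reads with more than 1 position were left out.

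The reference annotation at hand is on BDGP6 (dm6), another build than the deposited positions, and no genome sequence came with it. Positions were not converted between builds, so gene names, exons, the MSL2 gene and the gene lists fixed before the data were examined were not analysed here. Transcribed units took the place of genes. Each library was thinned to 4668708 arm reads, the libraries were pooled, and reads were tallied in bins of 100 bp per strand. A hidden Markov model with 2 states and a switch probability of 0.001 then called units of at least 500 bp. That probability was chosen after the reads were examined and before the treatments were compared. A unit can join neighbouring genes of 1 strand, can hold the region past a gene's end, and a long gene can be split into several units. Its start and end are given on dm3, counted from 1. Read density rose sharply at the upstream end of units and tapered at the downstream end, so reads were taken to run in the direction of the RNA. In control replicate 1, density relative to the unit mean was 3.22 from 100 to 200 bp after the start and 0.28 in the last 100 bp, over 4599 units of at least 3000 bp.

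The design fixed beforehand had planned a count test per gene, with limma voom in its place where the deposited files do not hold counts. The files hold alignments, so limma voom was applied to reads tallied per unit. Units were kept when at least 2 libraries reached the CPM that 10 reads have in the median library, with at least 15 reads in all, which left 7040. Library sizes were scaled by the trimmed mean of M values over all units, trimming 30% of log ratios and 5% of abundances. The factors were 0.977 and 0.990 for the control libraries and 1.02 and 1.01 for the MSL2 RNAi libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Sets of units were tested with camera in limma with a preset correlation of 0.01 and with an estimated correlation. The preset test takes its degrees of freedom from the number of units, so its very small p-values do not rest on the number of libraries. With an estimated correlation the degrees of freedom come from the libraries. Leaving out a library or adding a block lowers them. The share of X reads and the density ratio were tested by exact two-sided permutation of the libraries.

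For windows, log2 reads per kb with a pseudocount of 1 read were fitted by limma. Windows were the first 500 bp of units of at least 2000 bp, and the first and last 25% of the remaining length. The elongation index is the log2 ratio of last to first 25%, and the pausing index that of the first 500 bp to the rest.

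The naming rule, fixed beforehand for genes, took the 10 largest decreases and 10 largest increases past the adjusted threshold. They needed at least 100 reads on average and both MSL2 RNAi libraries on 1 side of both controls. It added the 5 most abundant X units and the 5 most abundant autosomal units past the threshold. No unit met it, so an unadjusted p under 0.001 replaced the threshold, a choice made after the values were seen.

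The fits were tested on simulated data with the libraries' depths and a dispersion of 0.0243, in 5 simulations of each kind. For the comparison of MSL2 RNAi with control, 200 of 7036 tested units were changed. They were drawn from units with at least 100 reads on average, and every unit had the same dispersion. Recovery in the real libraries can be lower, where 2R:2336001-2338500, with a log2 fold change of 2.71, had an adjusted p of 0.0663 in limma voom. In the simulations, 83.0% of units changed by 1 on the log2 scale and 100% of those changed by 2 were recovered, with a mean of 8.8 unchanged units called. An X shift of -0.5 was recovered as -0.51 to -0.49. Lowering the last 25% of X units by 0.4 was recovered as an elongation index change of -0.42 to -0.39.

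Alternatives covered scaling, filters, lanes, mismatches, pile-ups, overlaps, unit calls, window sizes, pseudocount, GC content and left-out libraries. Units called with switch probabilities of 1e-05 and 1e-09, on control libraries, or divided at internal rises, tiles of 5000 bp, the mismatch limit, limma trend, the GC correction and its combination with other settings were added after the data were seen. Depth ranged from 4771143 to 22447715 reads per library, so that the shallower replicate 2 limits the precision of units with few reads. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.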

Results

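Nascent RNA was measured by global run-on sequencing (GRO-seq) in Drosophila SL2 cells, a cell line of male embryonic origin. In this assay, engaged RNA polymerases extend their transcripts in isolated nuclei, and the RNA made in that step is purified and sequenced. Cells had been treated for 6 days with RNAi against MSL2 or, as a control, against GFP, a protein that fly cells lack. MSL2 is a subunit of the male-specific lethal complex, which binds the single male X chromosome and raises its transcription. Each treatment had 2 biological replicates, so the series holds 4 libraries, which had been sequenced in 12 lanes in all. The control libraries held 20571640 reads (replicate 1) and 4771143 reads (replicate 2). The MSL2 RNAi libraries held 22447715 and 6083664 reads. Replicate 2 of both treatments was therefore the shallower library.

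The aligned reads carry dm3 positions and no gene names, so the items compared are chromosome arms and transcribed units. A unit is a stretch of 1 strand with reads above background, called on the pooled libraries without regard to treatment. There were 7046 units, with a median length of 4800 bp. They held 98.0% of the reads on the chromosome arms and covered 26.6% of the bases of both strands. The RNA of the msl-2 gene itself was not analysed here, because a gene annotation on dm3 was not at hand.

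The first comparison asked whether the X chromosome as a whole lost nascent transcription when MSL2 was depleted. Reads on the X made up 13.1% ± 0.291 (SD, n = 2) of the reads on the 6 arms in control cells and 11% ± 0.0793 (SD, n = 2) after MSL2 RNAi. The share thus fell by 2.13 percentage points, which is many times the SD of either group. The values were 13.3% and 12.9% in the control libraries and 11.1% and 10.9% in the MSL2 RNAi libraries. The shares of 2L, 2R, 3L and 3R were each higher in both MSL2 RNAi libraries than in both controls, with differences of 0.485, 0.730, 0.249 and 0.704 percentage points. The shares of the 6 arms have a fixed sum, so a fall on the X raises the others. These differences do not show that autosomal transcription rose. Chromosome 4 held 1.07% ± 0.205 (SD, n = 2) of the arm reads in controls and 1.03% ± 0.215 (SD, n = 2) after MSL2 RNAi, a difference within the replicate spread. Its share was slightly lower within each replicate number, with 0.927% and 1.22% in controls and 0.876% and 1.18% after MSL2 RNAi. For the X, the exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 can give.

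Read density gave the same order of groups. Over tested units, the median density of X units divided by that of autosomal units was 0.786 ± 0.0192 (SD, n = 2) in controls and 0.618 ± 0.0316 (SD, n = 2) after MSL2 RNAi. The control libraries gave 0.800 and 0.773 and the MSL2 RNAi libraries 0.641 and 0.596. The log2 ratio of the group means was -0.35, and the exact two-sided permutation p was again 0.333.

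**Figure D1:**
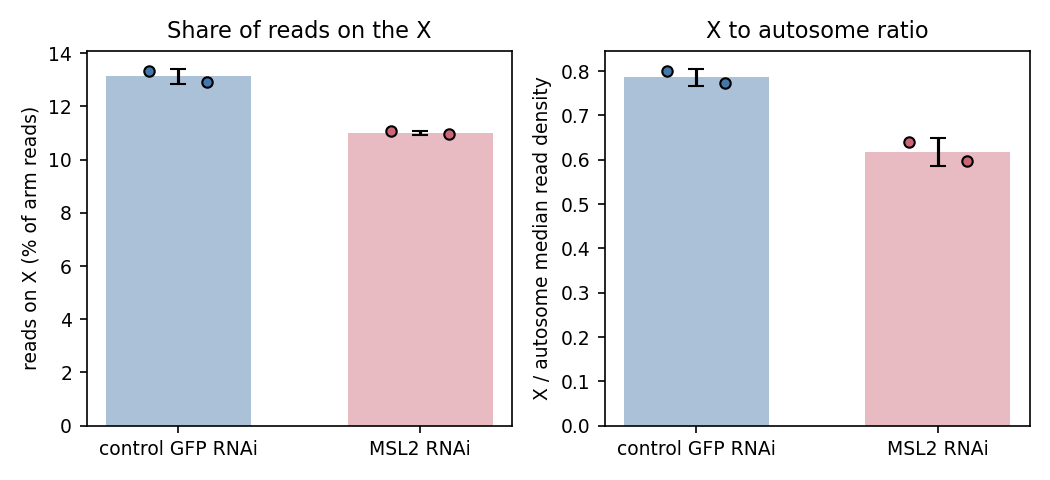
Share of arm reads on the X (left, percent) and the ratio of median read density of X units to autosomal units (right, no unit) in control GFP RNAi and MSL2 RNAi cells. Points are the 2 libraries of each treatment, bars their mean and error bars the SD. Both MSL2 RNAi libraries lie below both controls in each panel, with X shares of 11.1% and 10.9% against 13.3% and 12.9%.

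The second comparison asked which arms and units changed. X units fell as a group relative to autosomal units. The median log2 fold change of MSL2 RNAi over control was -0.28 over 1279 X units and 0.05 over 5664 units of 2L, 2R, 3L and 3R. The difference of -0.33 corresponds to nascent transcription 20.6% lower on the X relative to the autosomes. It lay between -0.40 and -0.30 in the 4 pairings of an MSL2 RNAi library with a control library, while the libraries of 1 treatment differed by -0.04 in both groups. Of the X units, 81.9% had a fold change below 0, against 39.6% to 42.3% on 2L, 2R, 3L and 3R and 65 of the 97 units of chromosome 4. The X set passed the camera test with its preset correlation (p = 3.34e-24) and with an estimated correlation (p = 0.00413). The X minus autosome difference was -0.31 without control replicate 1 and -0.37 without control replicate 2. It was -0.39 without MSL2 RNAi replicate 1 and -0.33 without MSL2 RNAi replicate 2. Leaving out a library also lowers the degrees of freedom of the test with an estimated correlation. Its p then rises even where the difference holds, so it cannot show whether the call depends on 1 library.

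Among the 6 arms, the X fell, with an adjusted p of 5.02e-23 with the preset correlation and 0.0252 with an estimated correlation. The test sets each arm against all other units, so that for an autosomal arm these include the lower X units, and a place above them does not show that the arm itself changed. Units of 2R, with a median log2 fold change of 0.04, and of 3R, with 0.06, ranked above the rest. Their adjusted p-values were 0.0415 and 0.0252 with the preset correlation and 0.0358 and 0.0317 with an estimated one. Units of 3L also ranked above the rest by the preset test, with a median of 0.05 and an adjusted p of 0.0415, but the adjusted p was 0.0576 with an estimated correlation. Units of 2L did not pass the preset test, with a median of 0.05 and an adjusted p of 0.0535 (0.0471 with an estimated correlation). The 97 units of chromosome 4 had a median of -0.13 and an adjusted p of 0.0415, which was 0.734 with an estimated correlation. Their median was -0.11 in both pairings of libraries with the same replicate number, but -0.59 and 0.32 in the other pairings. These directions are relative to the scaling over all units. With scaling on autosomal units, 2 arms were called, the X and 3R, and the median of 2R was -0.0039, on the other side of 0. The medians of 2L, 3L and 3R were then 0.00040, 0.0057 and 0.014, and that of the X was -0.33. Leaving out control replicate 1, control replicate 2, MSL2 RNAi replicate 1 or MSL2 RNAi replicate 2 left 2, 2, 1 and 3 arms called, the X among them each time.

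**Figure D2:**
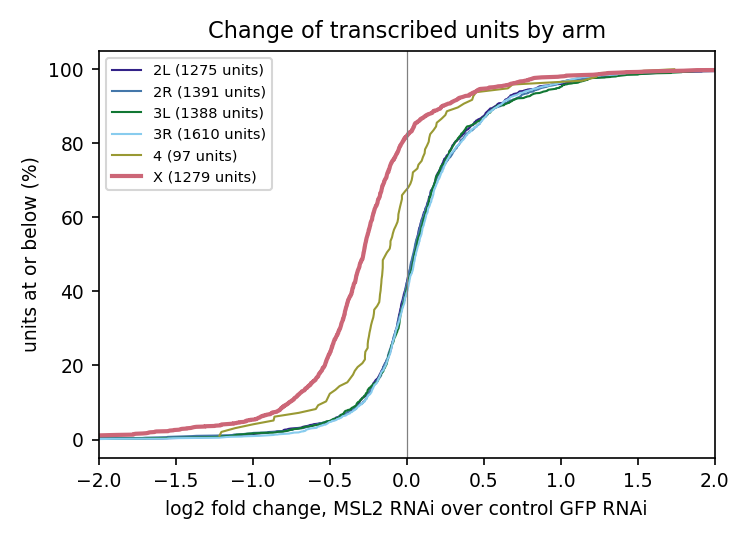
Cumulative share of units (percent) against log2 fold change of MSL2 RNAi over control GFP RNAi, with 1 line per chromosome arm. The line of the 1279 X units lies to the left of the autosomal lines over most of the range, with medians of -0.28 for the X and 0.04 to 0.06 for 2L, 2R, 3L and 3R.

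The lower level of the X was spread over its length. In 5 equal parts of the chromosome, the median log2 fold change of X units minus that of autosomal units was -0.31, -0.35, -0.37, -0.33 and -0.33. The ranges over the library pairings overlapped, and 77.1% to 84.7% of the units in each part had a fold change below 0. Units were also divided into 3 groups of equal size by mean log2 CPM. The X minus autosome difference was -0.49 in the lowest, -0.31 in the middle and -0.33 in the highest group. In the lowest group the autosomal units had a median of 0.23, while X units had -0.26. By length the differences were -0.36 for units up to 2800 bp, -0.33 for 2900 to 7900 bp and -0.35 for units from 8000 bp.

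With treatment as the only term, no single unit passed an adjusted p of 0.05 in limma voom. The smallest adjusted p was 0.0663 among 7040 units tested. At an unadjusted p under 0.05, 433 units were lower and 422 higher, and limma trend on log2 CPM also called 0 units in either direction. The 433 lower units included 253 of the X, and the 422 higher ones included 35. Without control replicate 1, control replicate 2, MSL2 RNAi replicate 1 or MSL2 RNAi replicate 2, the numbers called lower were 80, 39, 35 and 38. The numbers called higher were 28, 40, 86 and 59. With log2 values corrected for GC content, 15 units were called lower and 17 higher, and in the 8 lanes of the shared flow cell 1 was called lower and 5 higher. The absence of calls also depended on the terms of the fit. With the replicate number as a block, units were called in both directions, as given below with the other settings.

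The units named next were therefore chosen after their values were seen, by the naming rule with an unadjusted p under 0.001 in place of the adjusted threshold. It held for 11 units with lower and 21 with higher signal, of which 7 and 2 were on the X. The X held 1279 of the 7040 units tested. The X units among the lowest fold changes included 4 plus-strand neighbours. Whether these are parts of 1 long transcript stays open, so they may not count as separate units. X:12211201-12227200 had 39.5 ± 11.6 CPM (SD, n = 2) in controls and 9.26 ± 2.25 CPM after MSL2 RNAi, a log2 fold change of -2.09 (SE 0.31). X:12176901-12183400 had a log2 fold change of -2.08, X:12139701-12166100 of -1.96 and X:12111701-12137700 of -1.47 (SE 0.18), with adjusted p-values in limma voom from 0.0757 to 0.0881. Further X units were X:17108601-17113800, plus strand, with -1.89, and X:11467701-11480100, plus strand, with -1.51. The latter had 346 ± 11.6 CPM (SD, n = 2) in controls and 119 ± 39.6 CPM after MSL2 RNAi, but its fold change was -0.96 when at most 5 reads per position were counted. The most abundant X unit of the selection, X:2359201-2439500 on the minus strand, had 873 ± 99.6 CPM (SD, n = 2) in controls and 457 ± 51.6 CPM after MSL2 RNAi, a log2 fold change of -0.93 (SE 0.15).

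**Figure D3:**
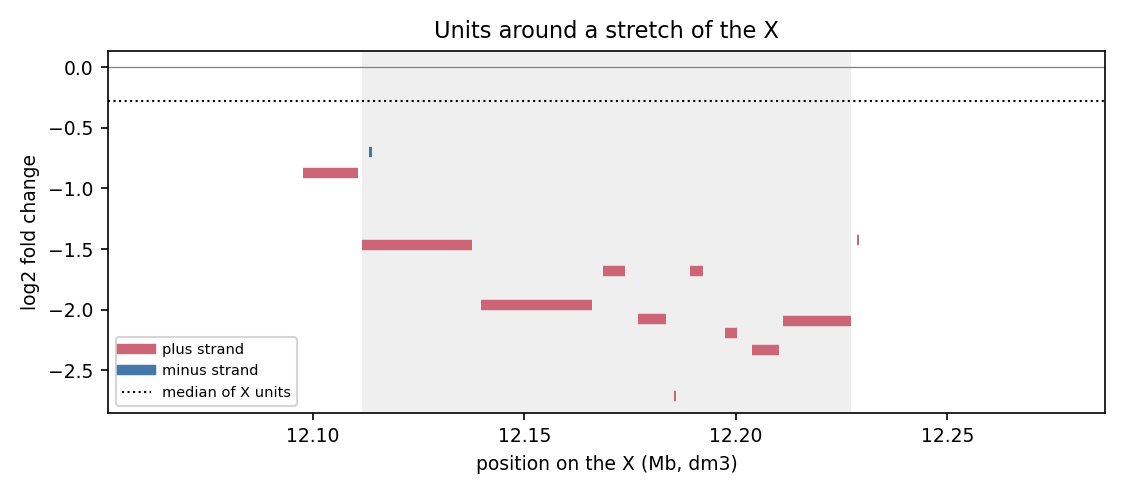
Log2 fold change of MSL2 RNAi over control GFP RNAi for units around X:12111701-12227200 (shaded), against position in Mb on dm3. Bars span units of the plus and minus strand, and the dotted line is the median of X units, -0.28. All 10 units in the shaded stretch lie below that line, the 4 named ones from -2.09 to -1.47.

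Autosomal units with low fold changes were 3L:4093201-4096200, plus strand, with -2.02, 3L:15003101-15007700, plus strand, with -1.69, 3L:10772901-10780200, plus strand, with -1.44, and 2R:9944801-9981000, minus strand, with -1.24. The last had 363 ± 32.1 CPM (SD, n = 2) in controls and 154 ± 12.2 CPM after MSL2 RNAi.

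Of the 10 units with the highest fold changes, 9 were autosomal. The minus-strand unit 2R:2336001-2338500 had 4.82 ± 0.259 CPM (SD, n = 2) in controls and 32.9 ± 3.41 CPM after MSL2 RNAi, a log2 fold change of 2.71 (SE 0.27, adjusted p = 0.0663 in limma voom). The minus-strand unit 2L:6317501-6325000 had 5.75 ± 0.327 CPM (SD, n = 2) in controls and 28.7 ± 0.261 CPM after MSL2 RNAi, a log2 fold change of 2.29 (SE 0.25). On 3R, the plus-strand units 25958201-25961300 and 22748901-22758900 had 2.15 and 1.64, and the minus-strand units 13483001-13484300 and 1970201-1973100 had 1.74 and 1.62. The plus-strand units 2R:12274001-12274500, 2R:16545301-16546400 and 2L:7926601-7927100 had 2.50, 1.99 and 1.92. The unit on the X among them, 13964601-13965400 on the plus strand, had 1.71. Without control replicate 1, the log2 fold change of 2R:16545301-16546400 was 1.34 instead. Counting at most 5 reads per position gave 2.02 for 2R:2336001-2338500, 1.57 for 2R:12274001-12274500, 1.21 for 2R:16545301-16546400 and 1.11 for 3R:13483001-13484300.

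The autosomal units with the highest abundance in the selection, besides 2R:9944801-9981000, all had fold changes above 0. The plus-strand unit 3L:7150701-7161000 had 119 ± 27.2 CPM (SD, n = 2) in controls and 292 ± 14.3 CPM after MSL2 RNAi, a log2 fold change of 1.36 (SE 0.19). The plus-strand units 2L:20104701-20105400, 2L:18153101-18155100 and 3L:1925401-1925900 had 1.61, 1.54 and 0.93. Counting at most 5 reads per position gave 0.60, 0.71 and 0.15 for them, a limit that in the shortest units also lowers a difference spread over all positions. For 2L:18153101-18155100, reads beyond the first 500 bp alone gave 0.62 (adjusted p = 0.474 in limma voom).

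The third comparison asked where along a unit the change lay, a question the series title raises by naming transcriptional elongation. It used the 968 X units and 4299 autosomal units of at least 2000 bp. In the first 500 bp the X minus autosome difference was -0.29, with a range over the 4 library pairings of -0.35 to -0.23. In the first 25% of the rest it was -0.29 (range -0.34 to -0.26), and in the last 25% it was -0.52 (range -0.54 to -0.48). The last part thus lay 30.3% lower on the X relative to autosomes. With each unit weighted alike, the difference was -0.45 in the first 100 bp, with a range of -0.62 to -0.25 that overlaps those of all other parts, and -0.30 both between 100 and 500 bp and between 500 and 1000 bp. Over 4 equal parts of the remaining length it was -0.31, -0.36, -0.44 and -0.51. The last part and the first 25% of the rest passed camera with adjusted p-values over 6 measures of 1.71e-22 and 2.84e-12 with the preset correlation and 0.00906 and 0.0309 with an estimated one. The first 500 bp had an adjusted p of 5.31e-09 with the preset correlation and 0.148 with an estimated one. The whole unit beyond 500 bp had a difference of -0.35, with adjusted p-values in camera of 1.60e-25 and 0.0605, so it did not pass with an estimated correlation.

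The elongation index, the log2 density of the last 25% over that of the first 25% beyond 500 bp, needs no scaling between libraries. On the X its median was -0.68 and -0.61 in the control libraries and -0.98 and -0.89 in the MSL2 RNAi libraries. On the autosomes it was -1.04 and -1.0 in controls and -1.11 and -1.08 after MSL2 RNAi. The index fell on the X by more than on autosomes, with a difference of -0.18 (range -0.25 to -0.17), or 11.9% on a linear scale. Its adjusted p in camera was 0.000396 with the preset correlation and 0.0309 with an estimated one. With units divided at internal rises, the unadjusted p with an estimated correlation was 0.0701. Leaving out any 1 of the 4 libraries gave differences between -0.24 and -0.16. Each such fit has fewer degrees of freedom, which alone raises the p with an estimated correlation. Whether the call needs all 4 libraries can therefore not be told from these fits.

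The pausing index, the log2 density of the first 500 bp over that of the remaining unit, had an X minus autosome difference of 0.07 (range 0.03 to 0.08) and did not pass camera (adjusted p = 0.365). On autosomes the first 500 bp had a median log2 fold change of 0.22. Its median log2 density was 3.04 and 3.28 in the control libraries and 3.29 and 3.49 in the MSL2 RNAi libraries. Each MSL2 RNAi library thus lay above the control of the same replicate number, while control replicate 2 lay at the level of MSL2 RNAi replicate 1.

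**Figure D4:**
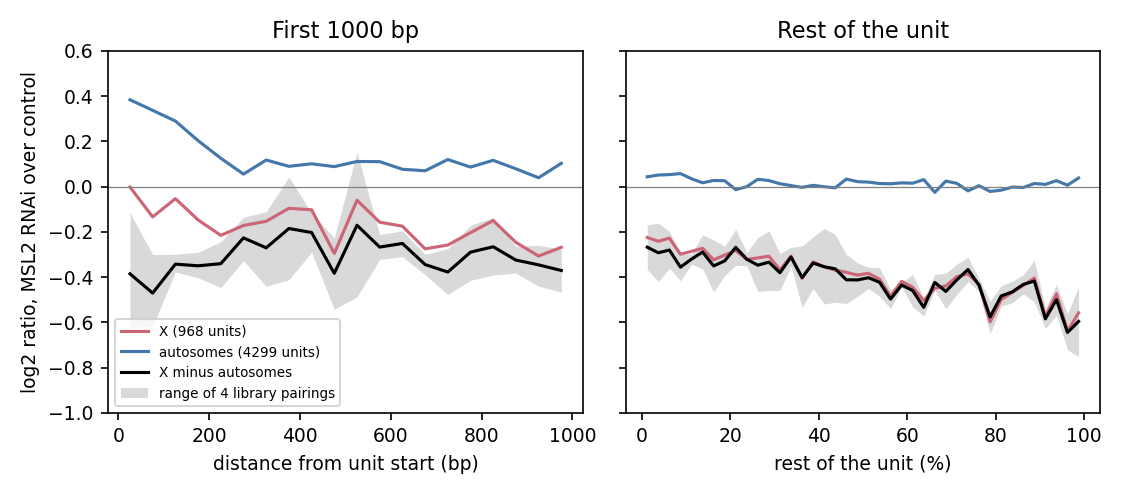
Log2 ratio of MSL2 RNAi over control GFP RNAi along units of at least 2000 bp, over the first 1000 bp (left, distance in bp) and the remaining length (right, percent), each unit weighted alike. Lines give X units, autosomal units and their difference, and the band is the range over the 4 library pairings. The difference was -0.45 over the first 100 bp, -0.30 in both parts between 100 and 1000 bp, -0.31 over the first and -0.51 over the last of 4 equal parts of the remaining length, while the autosomal line stayed near 0 there.

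In the 8 lanes of the flow cell that held all 4 libraries, the X minus autosome difference was -0.34 over whole units, -0.51 over the last 25% and -0.19 for the elongation index. Lane 1 of replicate 1 and lane 1 of replicate 2 came from 2 other instruments, each of which carried both treatments.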

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

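The alternatives with other unit calls, tiles, the mismatch limit, limma trend, the GC correction, settings combined with a block, and windows limited to units with their highest bin near the start or of at most 20 kb were chosen after the data were seen. The X minus autosome difference kept its direction and its side of the threshold with the preset correlation under all 26 alternatives, between -0.39 and -0.31. So did the changes of the 5' window (-0.40 to -0.24), the 3' part (-0.63 to -0.46) and the elongation index (-0.24 to -0.13) under 20 alternatives each. The difference in the share of X reads lay between -2.33 and -1.92 points under 9 alternatives, and the log2 density ratio between -0.40 and -0.30 under 13. None of the 25 named units changed direction in the alternatives that kept the units, though their selection by a small p made such a change unlikely. With a pseudocount of 5 reads the pausing index had a difference of 0.10 and passed camera with the preset correlation (unadjusted p = 0.0472). It did not pass with an estimated correlation (p = 0.745), and the cause was not tested. With that pseudocount the p with an estimated correlation was 0.0574 for the 3' part and 0.0735 for the elongation index. For the elongation index this camera p was 0.0701 for units divided at internal rises and 0.0652 for units with their highest bin in the first 500 bp. For the 3' part it was 0.0528 with at most 5 reads per position.

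Counts depended on the setting, and the cause was not tested. No unit was called in the main test. Without lane 1 of each library 1 was lower and 5 higher, with at most 1 mismatch 3 were higher, and with the GC correction 15 were lower and 17 higher. Leaving out 1 library, which assumes that the lone library varies like the others, gave 35 to 80 lower and 28 to 86 higher units. The number of arms called was 5 in the main test. It was 2 with scaling on autosomal units, 3 with at most 5 reads per position, 2 with libraries thinned to the smallest, 2 for units that overlap no unit on the other strand, 1 for units divided at internal rises, 2 for tiles of 5000 bp, and 1 to 3 without 1 library.

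The labels give both treatments replicates 1 and 2, with no word that a number marks a shared batch. Read names place the first lanes of the same number on the same instrument in both treatments. They do not show whether the cultures were handled together. Deviations from the group means of libraries with the same number had a correlation of 0.57 across units, which are not independent. Between single lanes of the shared flow cell, libraries with the same number were also more alike across treatments than libraries of 1 treatment were. With the replicate number as a block, 532 units were lower and 460 higher, 327 and 36 of them on the X. The blocked fit called 571 and 491 with the GC correction and 598 and 509 without lane 1. The X minus autosome difference was -0.34 with the block, the share of X reads -2.13 and the density ratio -0.35. Window differences had the same values with the block. The camera p with an estimated correlation was then 0.0485 for the 3' part and 0.0594 for the elongation index, against 0.00151 and 0.0113 without it. The block lowers the degrees of freedom of that test, which alone raises its p, so the larger values do not by themselves show a weaker change.

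The edgeR and DESeq2 tests of gene counts, and counts over exons or over genes without overlaps, were planned but not run, for lack of gene models on dm3. Depth limits units with few reads. Only 138 X units had no other unit within 1000 bp, and there the elongation index had an estimated-correlation p of 0.158.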

Other observations

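The tests of X copy number, and those of minus-strand reads, longer unit calls and read number in a stretch of the X, were chosen only after the results they bear on were seen. Outside the 6 arms, reads on the X heterochromatin sequence made up 0.0493% ± 0.00139 (SD, n = 2) of all reads in controls and 0.0427% ± 0.00164 (SD, n = 2) after MSL2 RNAi, lower in both libraries than in both controls (exact permutation p = 0.333). Shares on the other heterochromatin sequences, the unplaced sequences and the mitochondrial genome overlapped between treatments. The share on 3RHet was 0.341% and 0.557% in controls and 0.365% and 0.743% after MSL2 RNAi, a wider spread within than between treatments, though higher after MSL2 RNAi within each replicate number. Arm reads outside the tested units were 1.89% and 1.94% in controls and 2.15% and 2.35% after MSL2 RNAi.

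Runs of neighbouring units with raised signal lay near the proximal ends of 2R and 3L. The highest mean log2 fold change over 10 neighbouring units was 1.06 on 3L, at 23583701 to 23643500, with all 10 units above 0 and a range over the library pairings of 0.91 to 1.36. It was 0.96 on 2R, at 2048901 to 2078800, again with all 10 units above 0 (range 0.52 to 1.44). Mean abundance was 4.31 CPM in the first run and 17 CPM in the second. Both were chosen after their values were seen, as the highest of their arm, and no test was made of them.

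Reads on the X fell relative to the autosomes after MSL2 RNAi, and 3 technical explanations were weighed. A correction for GC content left a difference of -0.33 (range over the pairings -0.37 to -0.32) and the lanes of the shared flow cell alone gave -0.34 (range -0.40 to -0.31), which argues against a GC trend or the sequencing run as the whole cause. Fewer X copies in the treated cultures would lower all parts of a unit alike, whereas the elongation index changed by -0.18 on the X relative to autosomes, on 1 side of 0 in all 4 pairings. That argues against copy number as the whole cause, though its p in camera with an estimated correlation, 0.0113, rests on 2 libraries per treatment. For units divided at internal rises this camera p was 0.0701. A smaller loss of copies beside another cause stays open. Loss of MSL2, the treatment itself, stays open as a hypothesis that 2 libraries per treatment cannot separate from other differences between the cultures.

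The lowest mean over 10 neighbouring X units was -1.89, at 12111701 to 12227200, with all 10 units below 0, 9 of them on the plus strand. The lowest mean in 10000 shuffles of X units was -1.33, which gives a shuffle p of 0.0001, the smallest they can give. The shuffles take the units as separate. They therefore argue against chance clustering only if the units are separate transcripts, a question left open below. The 3 units with at least 1000 reads had a median of -1.96, which argues against few reads. Plus-strand reads there had a log2 fold change of -1.72 (range over the pairings -1.90 to -1.53). Minus-strand reads, 135 and 47 in controls and 88 and 36 after MSL2 RNAi, had -0.78 (range -1.39 to -0.17, counting interval -1.14 to -0.41). They thus fell less than plus-strand reads. Only 55 and 17 of them in controls and 35 and 16 after MSL2 RNAi lay in the 1 minus-strand unit of the stretch. So few reads over 115500 bp need not follow copy number, so a loss of copies of the stretch, whole or partial, stays open. The test on minus-strand reads replaced an earlier one on the spread of the 10 units, whose chi-square per degree of freedom of 2.11 lay too close to its bound of 2 to decide. Whether 1 long transcript was called as several units stays open, since 2 plus-strand units covered the stretch in the longest unit calls, 3 in the longer ones and 7 in those on control libraries, and the longest calls merged units everywhere, from 7046 to 3796 in all.

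A further hypothesis was that X units near GA repeats, a motif known at binding sites of the male-specific lethal complex, would fall more. Across 1279 X units, which are not independent replicates, the rank correlation of log2 fold change with the distance to the nearest run of 5 GA repeats was 0.0762, inside the central 95% of 10000 circular shifts (-0.0436 to 0.0823). That would have counted against the hypothesis by the bound set beforehand, but the value lay so near the upper limit that a weak relation is not excluded, and only bases covered by reads could be searched. On 2L, 2R, 3L and 3R the correlation with GA repeats was 0.0642, 0.0103, 0.0828 and 0.0268, each inside the central 95% of 1000 shifts. A value of this size was therefore not particular to the X. For 5 CA repeats the correlation on the X was 0.0718, also inside its shifts (-0.0102 to 0.104). On 3L that with CA repeats was 0.129, above its shifts (-0.0142 to 0.116). With length and mean CPM taken out, that with GA repeats on the X was lower, 0.0198, inside its shifts (-0.0611 to 0.0592). Length and read number could thus account for much of the value. Since it lay inside its shifts beforehand, the test cannot decide this.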
